A study of Homo sapiens with 6 samples.

How the data were processed

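The data were RNA sequencing libraries from xenograft tumours of MHCC97L, an established human hepatocellular carcinoma line, 3 from the control group (Ctrl) and 3 from the group given recombinant human lumican (rhLUM). Lumican is a secreted small leucine-rich proteoglycan of the extracellular matrix. Groups and the replicate letters A, B and C were taken from the labels. Dose, route and duration are not given in the sources used here, nor is whether the 3 libraries of a group came from separate tumours. The p-values therefore measure only the spread between these samples, which may be technical. The labels name no sequencing batch or date, so no comparison within batches could be made.

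Per the labels' protocols, total RNA was taken from the xenografts, poly-A RNA was selected and made into libraries with the KAPA mRNA HyperPrep kit and 10 PCR cycles, and paired-end reads of 151 bases were sequenced on an Illumina NovaSeq. Per the submitters' processing notes, STAR 2.7.8, RSEM 1.2.31 and the human genome build GRCh38 were used. The annotation release, the use of strand in counting, and any removal of mouse reads from the host animal are not given in the sources used here. Reads of a host transcript that resemble a human one can therefore add to a value, and an antisense gene cannot be told apart from its partner.

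Per the file headers, the authors deposited TPM, each transcript's share of the library scaled to a common sum, 1 table per library, with 60725 rows in the same order, a gene symbol per row and no identifier. Each library summed to about 1000000 TPM and values had 2 decimals. TPM divides estimated reads by transcript length and by the library's sum, so it keeps no depth: the depth of the libraries is unknown, no counting interval can be given, and a rise in abundant genes lowers the share left for all others. A total of 2210 rows, under 313 symbols, shared their symbol with another row and were left out. They held 0.723 ± 0.019% of TPM in Ctrl and 0.456 ± 0.0057% in rhLUM (SD, n = 3). Within a group the median coefficient of variation of a gene with a mean of 1 to 10 TPM was 12.1% in Ctrl and 14.0% in rhLUM, and at 100 to 1000 TPM it was 2.23% and 2.40%, so changes of low genes are known less precisely.

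The design fixed before the data were examined assumed expected counts and named limma on log2 TPM as the test if the tables held TPM, which they did. Genes with a mean of at least 1 TPM over the 6 libraries were kept. limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with its variance trend and the group as the only term, leaving 4 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was the threshold. Adjusted p-values given for genes come from this fit. Fold changes are on the log2(TPM + 1) scale, rhLUM minus Ctrl, which understates the change of low genes. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so none was used for single genes.

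A total of 39 gene lists were written before the data were examined. The 34 lists with at least 4 tested members were compared with all other genes by limma's camera with a correlation between genes preset at 0.01, adjusted over the 34 lists. The test was repeated with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. Adjusted p-values given for lists come from camera. Counts of members are those of the fit over all genes. Where they differed when adjusted over the list alone, which was so for 3 lists, both are given. Named genes followed a rule set before the data were examined: LUM, the 10 genes with the largest change in each direction among those past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest p past the threshold. Unnamed clones and pseudogenes were left out. CXCL8, the members that moved against their list, AKR1C2, and the genes of the closing section that are not under the rule were chosen after their values were seen. Some genes that the rule or a count would name are not reported here.

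Coordinates, gene types, transcript lengths and GC content came from the GENCODE release 29 annotation of GRCh38, supplied as reference, matched by symbol. Its release may differ from the one the authors used. Length and GC content were found for 12837 of the 14781 tested genes (86.8%). Alternatives planned before the data were examined were median-of-ratios and upper quartile scaling of the TPM, a pseudocount of 0.1, no filter on low values, a replicate block, a test against a fold change of 1.2, rescaling without mitochondrial and other-cell genes, and leaving out each library. Those chosen after seeing the data were at least 1 TPM in all 6 libraries, shared symbols summed, limma without the trend, quantile normalization, rescaling without mitochondrial genes, and a loess correction of each library for GC content and transcript length with a span of 0.5. The loess correction also recentres each library, and it moved the median gene by -0.15 on the log2 scale.

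The fit was tested on simulated data for rhLUM against Ctrl, with 14781 genes of which 200 were changed. It recovered 70% of the 100 genes changed 1.5-fold and 88% of the 100 changed 2-fold, made 15 false calls and called 1 of 34 lists. Far fewer genes were changed than the 9870 called in the data, so these shares do not carry over to it. The noise was drawn independently for each gene, so the list count does not test the preset correlation.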

Results

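RNA was profiled in 6 xenograft tumour libraries of the human liver cancer line MHCC97L, 3 from controls (Ctrl) and 3 given recombinant human lumican (rhLUM). The comparison asks which transcripts of the tumour differ when the matrix proteoglycan lumican is supplied. Rows above 0 TPM numbered 23525 to 24060 in the Ctrl libraries and fewer, 22323 to 22916, in the rhLUM libraries. The depth behind the values is unknown. Libraries of a group correlated at 0.978 to 0.983 (6 pairs, Pearson's r of log2 TPM across genes, which are not independent replicates). Libraries of different groups correlated at 0.928 to 0.935 (9 pairs).

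With rhLUM, genes of the inflammatory response were among those that fell most in the tumours. The complement component C3 went from 422 ± 12.1 TPM in Ctrl to 5.74 ± 1.08 in rhLUM (SD, n = 3 per group), and the siderophore-binding protein LCN2 from 1423 ± 23.3 to 40.5 ± 1.80. The mucin MUC5AC and the secreted lectin REG4 rose the most among named genes whose symbol stands on a single row, MUC5AC from 0.38 ± 0.079 to 28.3 ± 1.14 TPM and REG4 from 0.84 ± 0.17 to 25.4 ± 1.46. Most tested genes of cholesterol and fatty acid synthesis, of the NRF2 oxidative stress response and of the cell cycle rose by smaller amounts, and most of the interferon response fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.0608 to 0.221). The estimate was below the preset 0.01 for the interferon (-0.00775) and fatty acid synthesis (0.00562) lists. Correlation between genes therefore does not account for the loss of those calls. A lost call is thus no sign of such correlation in the other lists. LUM, the gene of lumican itself, also rose.

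Of 14781 genes tested, 6571 were higher and 3299 lower with rhLUM (limma, adjusted p under 0.05), or 66.8% of all. At least a doubling was seen for 910 genes and at least a halving for 661. The 3 libraries of one group lay wholly above the 3 of the other for 71.4% of genes, against 10% by chance. The median gene stood at 0.16 on the log2 scale, and median-of-ratios scaling moved this median by -0.18. That scaling gave 4821 genes higher and 4825 lower, so the share of higher calls was 66.6% as deposited and 49.98% after it. Rescaling without mitochondrial genes, whose share of TPM was lower with rhLUM, moved the median by -0.11. It gave 5616 genes higher and 4225 lower (57.1% higher), so part of the excess of higher calls depends on the mitochondrial share. Small rises under about the size of the -0.18 shift depend on the scaling, and counts after scaling refer to median-of-ratios scaling.

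LUM, on chromosome 12 at 91102629 to 91111831 (GRCh38, minus strand, protein coding), rose from 24.7 ± 1.56 TPM in Ctrl to 95.5 ± 3.54 in rhLUM (SD, n = 3). Its log2 fold change was 1.91 (SE 0.05, limma adjusted p = 2.89e-07), and all 3 rhLUM libraries lay above all 3 Ctrl libraries. After median-of-ratios scaling it was 1.72. The protein given carries no RNA, so this value does not check the labels. Of 11 proteoglycans of the lumican family that were found, 9 had a mean under 1 TPM. DCN, which encodes decorin, fell from 7.96 ± 0.35 to 1.26 ± 0.32 TPM, a log2 change of -1.99 (limma adjusted p = 8.2e-06).

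**Figure D1:**
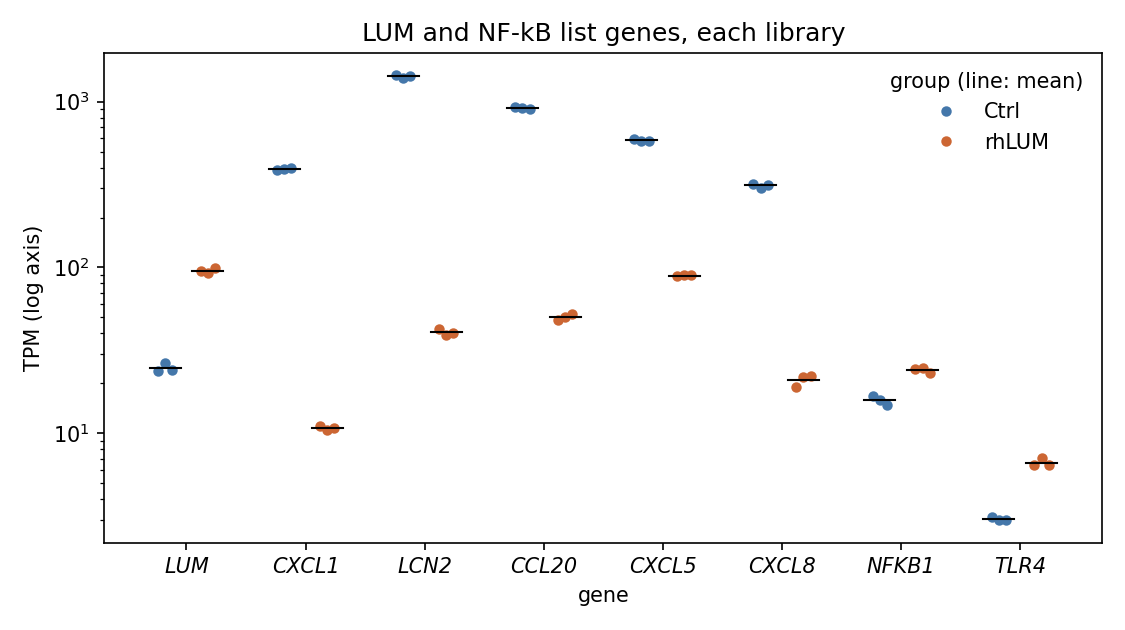
TPM of LUM and of 7 genes of the NF-kB list in each of the 6 libraries on a log axis, with points for libraries, colours for the groups and short lines for group means. LUM, NFKB1 and TLR4 lie higher in the rhLUM libraries and the 5 other genes lie lower, CXCL1 falling from a mean of 392 to 10.7 TPM.

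The other large rises included PGM5 (log2 fold change 2.86), related to phosphoglucomutase, and SULT1C4 (2.63), a sulfotransferase. SCARA3 (2.47), IGFL2 (2.45) and PRKCB (2.45), which encodes a protein kinase C, followed. CDH17, the liver-intestine cadherin, rose from 14.1 ± 0.10 to 76.5 ± 1.24 TPM and PDZK1, a scaffold protein of epithelial transporters, from 10.6 ± 0.99 to 56.1 ± 2.69 (SD, n = 3). SSTR5-AS1 (2.75) lies antisense to another gene, and the use of strand is not given. Among the falls, the lipopolysaccharide-binding protein gene LBP changed by -5.59 and haptoglobin, HP, by -4.95. IL6 and IL1B, which encode inflammatory cytokines, fell from 56.7 ± 1.63 to 0.52 ± 0.31 TPM and from 147 ± 1.58 to 4.30 ± 0.57 (SD, n = 3). SAA1 (-5.22), HP and the defensin DEFB4A have near-identical relatives with which reads can be shared. DEFB4A was listed at 23.2, 24.75 and 29.51 TPM in Ctrl and at 0 in all 3 rhLUM libraries. SNORD89, a short RNA that poly-A selection captures poorly, was listed at 32.05, 22.32 and 26.92 TPM in Ctrl and at 0 in rhLUM.

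Of the NF-kB and inflammatory response list, 21 of 23 tested members fell and 2 rose, with the same counts after median-of-ratios scaling. The median log2 fold change was -3.22, the list was lower than other genes (camera adjusted p = 3.51e-15), and it was the 1 list whose call held with an estimated correlation (adjusted p = 0.0266). The chemokine genes CXCL1, CCL20 and CXCL8 changed by -5.07, -4.16 and -3.83 on the log2 scale. CCL20 went from 917 ± 14.0 to 50.4 ± 2.03 TPM and CXCL5 from 585 ± 9.97 to 89.3 ± 0.49 (SD, n = 3). CXCL1 shares sequence with its neighbours of the same family. The members that rose were NFKB1 (0.58), a subunit of NF-kB itself, and TLR4 (0.92), the lipopolysaccharide receptor.

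Of 25 tested genes of the interferon response, 19 fell and 4 rose (19 and 2 after scaling), with a median of -0.56 and camera adjusted p = 5.77e-06. With an estimated correlation the adjusted p was 0.0608. B2M, the light chain of class I HLA molecules, fell from 3719 ± 28.1 to 2500.0 ± 13.1 TPM (SD, n = 3). HLA-B changed by -1.90, IFI27 by -1.51 and ISG15 by -0.91. The genes that rose were the antiviral OAS1 (0.51) and OAS3 (0.44), with IFIT1 (0.52) and DDX58 (0.27), whose calls were lost after scaling. The call of IFIT1 was also lost on leaving out any library but Ctrl C or rhLUM B (adjusted p up to 0.0782).

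Of 15 genes of the mitochondrial genome, 13 fell and 1, MT-ND5, rose (14 and 0 after scaling, under which MT-ND5 was at -0.077). The list's median was -0.47 (camera adjusted p = 8.55e-09, and adjusted p = 0.0608 with an estimated correlation). MT-CO2 changed by -0.59 and MT-ATP6 by -0.76. The mitochondrial share of TPM was 20.6 ± 0.078% in Ctrl and 14.4 ± 0.10% in rhLUM (SD, n = 3).

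All 16 tested targets of NRF2, a regulator of the oxidative stress response, rose, with a median of 0.68 (camera adjusted p = 1.32e-06, and adjusted p = 0.128 with an estimated correlation). After scaling 15 rose and 1, AKR1C2, fell. TXNRD1, a thioredoxin reductase, went from 743 ± 4.81 to 1746 ± 20.1 TPM (SD, n = 3). AKR1C1 changed by 0.98 and NQO1 by 0.72.

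Of 19 genes of cholesterol synthesis and its control, 18 rose and none fell (17 and 0 after scaling), with a median of 0.64 (camera adjusted p = 1.98e-05, and adjusted p = 0.198 with an estimated correlation). DHCR7, which acts in the last step, changed by 1.21 and FDFT1, squalene synthase, by 0.65. Of 13 fatty acid synthesis genes, 11 rose and 1, MLXIPL (-0.26, a call lost on leaving out any library but Ctrl A, adjusted p up to 0.116), fell (9 and 1 after scaling), with a median of 0.74 (camera adjusted p = 0.00563, and adjusted p = 0.198 with an estimated correlation). After a correction for transcript length and GC content 8 were higher and 1 lower, with a median of 0.37 (adjusted p = 0.0117). The desaturase FADS2 rose from 119 ± 3.67 to 379 ± 17.2 TPM (SD, n = 3), SCD changed by 1.15 and ME1, which is also on the NRF2 list, by 1.10.

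Of 22 DNA replication genes, 19 rose and 1, PCNA (-0.09), fell (16 and 1 after scaling), with a median of 0.55 (camera adjusted p = 8.15e-04, and adjusted p = 0.198 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose by 0.98, GINS1 by 1.00 and TYMS, thymidylate synthase, by 0.62. Of 20 mitosis genes, 17 rose and 1, TOP2A (-0.18), fell (16 and 3 after scaling), with a median of 0.56 (camera adjusted p = 0.00125, and adjusted p = 0.221 with an estimated correlation). The mitotic kinase PLK1 rose from 23.4 ± 2.05 to 70.4 ± 3.69 TPM (SD, n = 3), TPX2 by 1.25 and BIRC5 by 0.67.

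Of 15 genes of epithelial junctions and keratins, 11 rose and 3 fell (10 and 3 after scaling), with a median of 0.57 (camera adjusted p = 0.035, and adjusted p = 0.198 with an estimated correlation). The call was lost in limma without the trend (adjusted p = 0.073). The keratin KRT8 rose from 1060.3 ± 4.73 to 2474 ± 9.59 TPM (SD, n = 3), and the desmosomal DSP by 1.67. CLDN1 (-0.62), TJP3 (-0.77) and the adhesion molecule gene EPCAM (-0.74) fell. Of 21 integrin and focal adhesion genes, 16 rose and 2, ITGA3 and ITGA5, fell (14 and 4 after scaling), or 17 and 3 when adjusted over the list alone. The median was 0.51 (camera adjusted p = 0.0288, and adjusted p = 0.198 with an estimated correlation). ITGB1, ITGAV and ITGA6, which encode integrin subunits, changed by 0.79, 0.96 and 1.22. Fold changes went up with transcript length across genes, which are not independent replicates (Spearman 0.30), from a median of -0.10 in the shortest 10% of genes to 0.47 in the longest 10%. They went down with GC content (Spearman -0.16). A correction for length and GC content left 9 integrin genes higher and 4 lower, with a median of 0.13, and ended the call of that list (adjusted p = 0.199). Its call was lost too with at least 1 TPM required in all 6 libraries (adjusted p = 0.0533). The same correction gave medians of 0.33 for epithelial junctions, 0.36 for mitosis, 0.38 for DNA replication, 0.41 for cholesterol synthesis, 0.47 for NRF2 targets and 0.31 for the unfolded protein response. It also moved the median of all genes by -0.15. Lower list medians after it cannot be put down to length and GC content alone. Median-of-ratios scaling, which moved the median of all genes by -0.18, gave 0.38, 0.37, 0.36, 0.45, 0.48 and 0.29 for those lists in that order. These lie close to the corrected medians. For integrins, Wnt targets and fatty acid synthesis it gave 0.32, 0.42 and 0.54, above the corrected 0.13, 0.23 and 0.37. A shift of all genes alone does not account for the corrected medians of the latter.

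Of 11 Wnt target genes, 10 rose and 1, SP5 (-0.96), fell (7 and 1 after scaling), with a median of 0.57 (camera adjusted p = 0.0301, and adjusted p = 0.198 with an estimated correlation). After the correction for length and GC content 6 were higher and 1 lower, with a median of 0.23 (adjusted p = 0.0497). The Wnt inhibitor gene DKK1 rose by 1.29, CCND1 by 1.08 and CTNNB1, beta-catenin, by 1.04. Of 17 genes of the unfolded protein response, 14 rose and 3, CRELD2, HSP90B1 and CALR, fell (10 and 3 after scaling), with a median of 0.49 (camera adjusted p = 0.0301, and adjusted p = 0.221 with an estimated correlation). SEL1L rose by 1.21, HYOU1 by 0.75 and PDIA6 by 0.53, and the list's call was lost with upper quartile scaling (adjusted p = 0.0544) and with at least 1 TPM required in all 6 libraries (adjusted p = 0.0533).

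**Figure D2:**
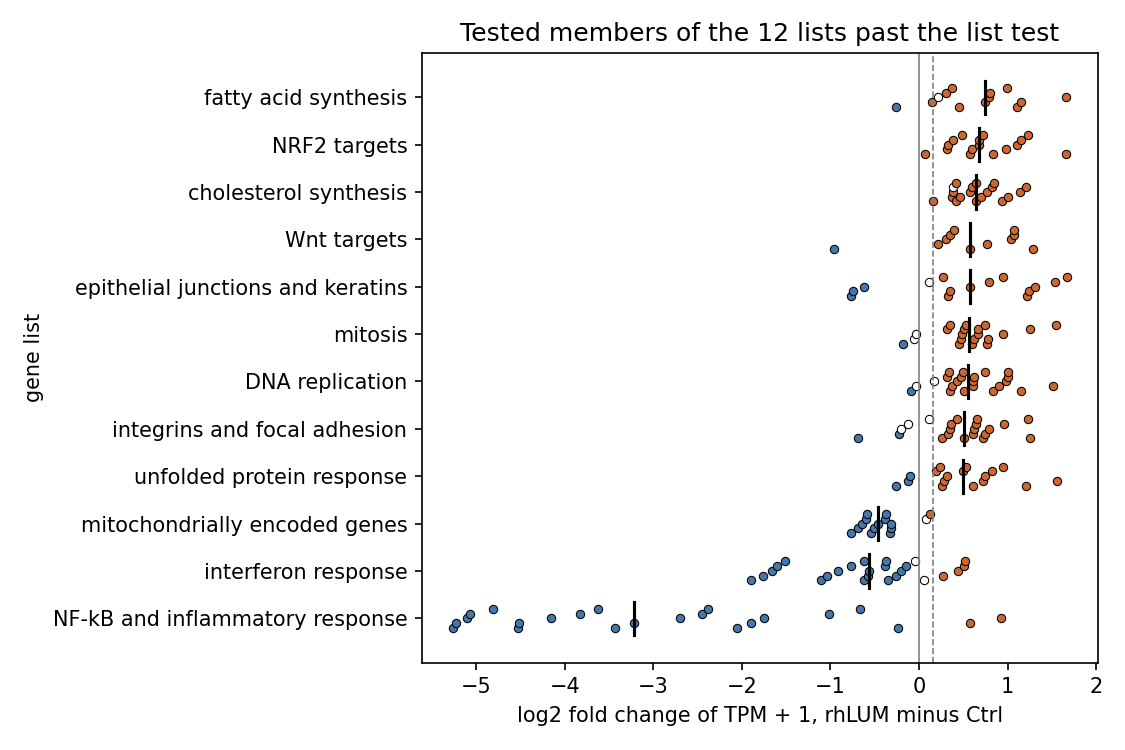
log2 fold change of TPM + 1, rhLUM minus Ctrl, for every tested member (points) of the 12 lists past the list test, with filled points past the per-gene threshold, orange higher and blue lower, and open points not past it. Thick lines are list medians, the dashed line is the median of all genes (0.16), and the NF-kB list has its median at -3.22 with 2 members above 0.

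The other 22 tested lists did not pass as deposited. Liver-specific genes went both ways: of 16 hepatocyte secreted proteins 8 rose and 7 fell (7 and 7 after scaling, adjusted p = 0.373), ALB rising from 289 ± 3.08 to 825 ± 15.4 TPM while the fibrinogen genes FGG and FGA changed by -2.13 and -1.67 (SD, n = 3). This list's median was 0.11, its mean -0.17 and its test pointed lower. Of 10 hepatocyte enzymes 4 rose and 2 fell (adjusted p = 0.886), with ASS1 at -3.01 and HNF4A at 1.07, and here too the median, 0.20, and mean, -0.08, differed in sign. Progenitor and stem markers had 6 higher and 9 lower of 17 (5 and 11 after scaling, adjusted p = 0.0832), among them POU5F1 (-2.39), CD47 (-1.22) and ALDH1A1 (0.57). Of 7 drug efflux transporters 6 rose and 1 fell (adjusted p = 0.103; 5 and 1 after scaling, 3 and 3 after the correction for length and GC content), with ABCG2 at 1.83 and ABCB1 at 1.21. Of 20 hypoxia genes 8 rose and 10 fell (7 and 12 after scaling, adjusted p = 0.102), ADM by -1.23 and DDIT4 by -0.88. Mesenchymal genes had 3 higher and 7 lower of 14 (adjusted p = 0.0903), with TGFBI at -1.01 and CDH2 at 1.08. The hypoxia list passed as lower after the correction for length and GC content (adjusted p = 0.0202), and the mesenchymal list as lower on rescaling without mitochondrial and other-cell genes (adjusted p = 0.0224). That setting also took SPARC (0.94), a fibroblast marker that rose, out of the mesenchymal list, so its gain is not one of rescaling alone.

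Fatty acid oxidation had 11 higher and 4 lower of 15 (10 and 4 after scaling, adjusted p = 0.204), HADHA of the mitochondrial trifunctional protein rising by 1.03. ERK targets had 13 higher and 3 lower of 19 (11 and 3 after scaling, adjusted p = 0.119), with EGFR at 1.45 and IER3 at -1.45. TGF-beta targets had 9 higher and 6 lower of 17 (7 and 7 after scaling, adjusted p = 0.886), TGFBR2 rising by 1.29. Matrix proteases had 6 higher and 6 lower of 17 (6 and 7 after scaling, adjusted p = 0.793), with MMP24 at 2.03 and MMP1 at -1.58, and nuclear respiratory chain genes 11 higher and 9 lower of 24 (6 and 12 after scaling, adjusted p = 0.497). YAP targets had 9 higher and 2 lower of 12 (7 and 3 after scaling, adjusted p = 0.266), with NT5E at 1.61. Glycolysis had 11 higher and 4 lower of 18 (11 and 7 after scaling, adjusted p = 0.201), ATF4 targets 11 and 6 of 18 (11 and 6 after scaling, adjusted p = 0.90), and Notch genes 4 and 4 of 8 (3 and 4 after scaling, adjusted p = 0.544). The balance of p53 targets turned, from 9 higher and 3 lower of 18 to 5 and 7 after scaling (adjusted p = 0.886). Handling and heat stress genes had 8 higher and 8 lower of 19 (4 and 11 after scaling, adjusted p = 0.266). The 4 of them with the smallest p went both ways, by 1.54, -1.76, -1.61 and 0.79. Replication-dependent histones had 6 and 1 of 9 (adjusted p = 0.313, and adjusted p = 0.0497 after the correction for length and GC content). The correction for length and GC content left more lower than higher for the p53 (5 and 8), TGF-beta (6 and 7), protease (6 and 8), Notch (2 and 4) and heat stress (7 and 9) lists. That correction also moved the median of all genes by -0.15, so these turns cannot be put down to length and GC content alone. It left 8 and 3 for ERK targets (median 0.47 before and 0.13 after it), 8 and 4 for fatty acid oxidation (0.62 and 0.22), 7 and 3 for YAP targets (0.52 and 0.20) and 11 and 7 for glycolysis (0.40 and 0.22). Median-of-ratios scaling gave these lists medians of 0.29, 0.43, 0.33 and 0.21 in that order. For the TGF-beta, protease, respiratory chain, Notch and heat stress lists the median was above 0 while the test against other genes pointed lower, and the mean was below 0 for the Notch and heat stress lists. Cytosolic ribosomal proteins had 11 higher and 13 lower of 27, or 12 and 13 when adjusted over the list alone (adjusted p = 0.178). After median-of-ratios scaling 5 were higher and 19 lower, and that list passed (adjusted p = 0.00246).

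Markers of other cells were mostly near 0. Of 21 leukocyte and macrophage markers 17 had a mean under 1 TPM, and of the 4 tested CD68 (0.77) and LYZ (0.42) rose while CD74 (-1.48) and ITGAM (-0.92) fell (adjusted p = 0.886). Of 20 fibroblast markers 8 were under 1 TPM, and of the 12 tested 6 rose and 4 fell (3 and 4 after scaling, adjusted p = 0.886), with LUM and SPARC (0.94) higher and COL6A3 (-1.97) and DCN lower. Of 15 endothelial markers 10 were under 1 TPM. Of the 5 tested 2 rose and 2 fell, or 3 and 2 when adjusted over the list alone (adjusted p = 0.793), with CDH5 at -1.50 and PECAM1 at 0.59. The fibroblast and endothelial lists had medians above 0, the endothelial list a mean below 0, and both tests pointed lower. After the correction for length and GC content these medians were -0.045 and -0.17. Too few members were tested for the remaining lists. TNNI2 of skeletal muscle changed by -0.91, PPARG and CIDEC of adipocytes by 0.65 and 1.07, and KRT10 and TP63 of keratinocytes by -0.37 and -0.45 (TP63 lost its call on leaving out any library but Ctrl A or rhLUM B, adjusted p up to 0.109), while the 1 tested red blood cell gene did not pass.

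Position along the genome was examined after the data were seen. Tested protein-coding genes were placed in 222 windows of 50 neighbouring genes (GRCh38), and each window's median log2 fold change was set against that of the genome. The medians of 7 windows lay beyond the 95% bound of the largest value in 1000 permutations of the genes (0.33), 2 higher and 5 lower. The lowest, on chromosome 1 at 923928 to 6101193, stood at -0.70, with 46 of its 50 genes below the genome median, and its neighbour at 6101793 to 11926428 stood at -0.51. A window on chromosome 3 at 184812143 to 196568674 stood at -0.45. The highest, on chromosome 20 at 25248069 to 35519280, stood at 0.42. TPX2, GINS1 and MMP24, named above with their lists, lie in this highest window, and ISG15 lies in the lowest. Whether their changes are separate from those of their windows was not tested.

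**Figure D3:**
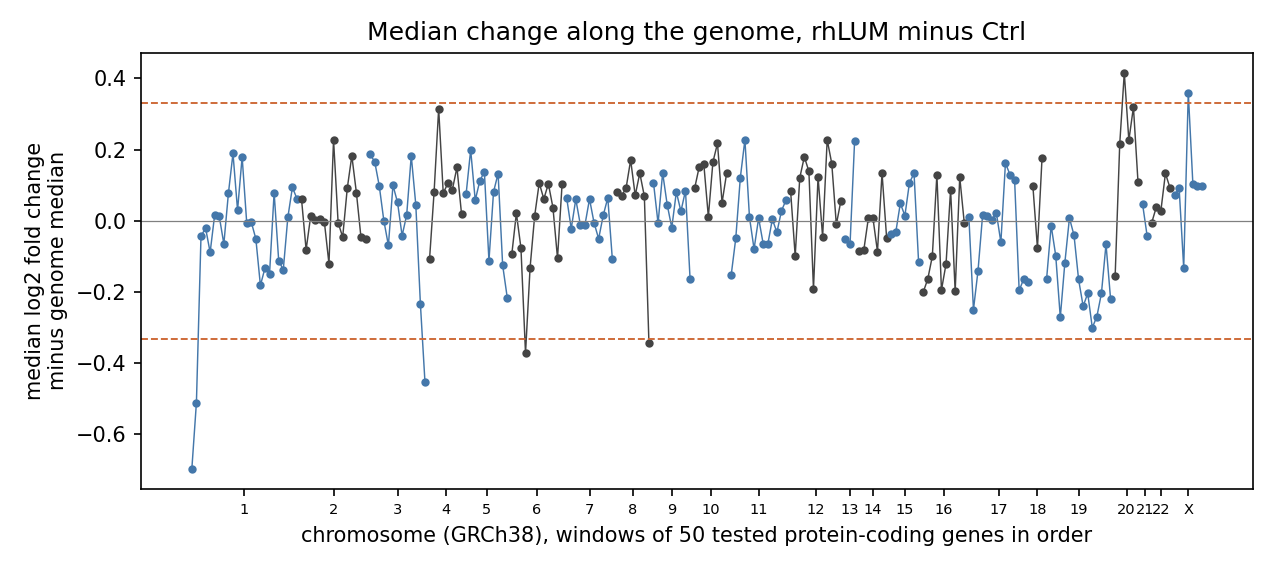
Median log2 fold change (rhLUM minus Ctrl) of each of 222 windows of 50 tested protein-coding genes, minus the genome median, in genome order with chromosomes in alternating colours. Dashed lines mark the permuted bound of 0.33 on either side, beyond which 7 windows lie, the lowest at the start of chromosome 1 (-0.70).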

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

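The tests named here were chosen after the values were seen. Both results come from rows that share a symbol with other rows, which the comparison left out and which were summed per symbol here. SNORA40, under 22 rows, had 0, 1.96 and 0 TPM in Ctrl and 15.38, 60.71 and 23.15 in rhLUM, a log2 fold change of 4.34 (limma adjusted p = 0.00774 over these symbols). RMRP, under 2 rows, had 20.9 ± 8.22 TPM in Ctrl and 66.6 ± 8.78 in rhLUM (SD, n = 3), a log2 fold change of 1.68 (limma adjusted p = 0.00929). Each was higher in all 3 rhLUM libraries than in every Ctrl library. Both are RNAs without a poly-A tail, which the library protocol selects against. Other such RNAs in the same rows were lower with rhLUM: SNORD22 went from 226 ± 54.9 to 20.7 ± 15.1 TPM (SD, n = 3), and SCARNA4, SNORA21 and U1 changed by -4.90, -1.74 and -1.25. SNORA33 and U3 were lower as well and listed at 0 in all 3 rhLUM libraries. No explanation was tested.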

How the results depend on the processing

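Settings chosen before the data were examined that need read counts, which are a negative binomial Wald test, voom and a minimum of 10 counts, were not run, and scaling by the total alone is what TPM already is. Chosen after seeing the data were GC and length correction, quantile normalization, rescaling without mitochondrial genes, limma without the trend and 2 others. Upper quartile scaling gave 5152 genes lower, and a test against a fold change of 1.2 gave 4190 higher and 1811 lower, as a stricter test must. The GC and length correction, with 12837 genes tested, gave 4370 higher. It also moved the median gene by -0.15, near the -0.18 of median-of-ratios scaling. Median-of-ratios scaling, with 14822 genes tested, gave 4821 higher, so a shift of that size lowers the count without a correction for GC content or length. The share of higher calls was 49.98% after that scaling and 51.5% after the correction, which tested fewer genes. Under the other alternatives both counts stayed within 1.5 times those reported. Without 1 library, 6187 to 6288 genes were higher and 2956 to 3172 lower. Of the genes called higher, 54 were called lower after median-of-ratios scaling and 246 after the GC and length correction.

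Of the 12 lists past the test, 1 passed with an estimated correlation. Among the lists lost, the estimate was below the preset 0.01 for interferon (-0.00775), fatty acid synthesis (0.00562), Wnt (0.00508), epithelial (-0.0393) and integrin (-0.0445) genes. Correlation between genes does not account for the loss of those lists. The estimate was above 0.01 for the other lists lost. Since lists with lower estimates were lost too, a lost call is no measure of correlation, for these other lists either. With fry, 32 of 34 lists passed. The lists lost in single settings were epithelial junctions without the trend (adjusted p = 0.073), integrins after the GC and length correction (0.199) and with at least 1 TPM in all 6 libraries (0.0533), and the unfolded protein response with upper quartile scaling (0.0544) and with at least 1 TPM in all 6 (0.0533). The other 9 stayed past it in every setting run with the preset correlation (16 for the mitochondrial list and 18 for the others), the highest adjusted p being 0.0497 for Wnt targets after the GC and length correction. Lists gained were, without a filter on low values, ERK targets (0.0025), drug efflux (0.00629), glycolysis (0.0324), histones (0.0324) and fatty acid oxidation (0.0438), all higher. The GC and length correction added hypoxia (lower, 0.0202) and histones (higher, 0.0497). Rescaling without mitochondrial and other-cell genes, which also took the rising SPARC out of the list, added mesenchymal transition (lower, 0.0224). Ribosomal proteins were gained as lower under 5 scalings (0.00107 to 0.0176).

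LUM kept its direction and call in every setting that gave it a value. Of 2156 values of 122 other named genes, 2105 kept direction and side of the threshold, 41 were no longer past it and 10 turned. AKR1C2 turned to -0.13 under median-of-ratios scaling, -0.17 under upper quartile scaling, -0.049 on rescaling without mitochondrial genes and -0.049 on leaving out other-cell genes too, -0.022 under quantile normalization and -0.24 under the GC and length correction. MT-ND5 turned to -0.077 and -0.11 under median-of-ratios and upper quartile scaling. Under the GC and length correction C5 stood at -0.10 and DDX58 at -0.077. The cause was not tested. Leaving out 1 library ended the call of IFIT1 in 4 of 6 fits (all but Ctrl C and rhLUM B, adjusted p up to 0.0782), of COL1A1 in 4 (all but Ctrl B and rhLUM B, up to 0.0873), of MLXIPL in 5 (all but Ctrl A, up to 0.116) and of TP63 in 4 (all but Ctrl A and rhLUM B, up to 0.109).

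The replicate letters were not used to pair libraries. Deviations from the group means of libraries with the same letter correlated at 0.03 for A, -0.02 for B and 0.08 for C, and B did not correlate best with its own letter. A replicate block gave 6429 genes higher, 3219 lower and 12 lists.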

Other observations

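A pair of gene groups outside the lists fixed beforehand was tested with lists written after the data were examined. They hold some of the genes that prompted them, so their tests are not independent evidence. Of 25 tested complement and acute-phase genes, proteins that the liver secretes in inflammation, 21 fell and 2 rose, with a median log2 fold change of -2.13 (camera adjusted p = 2.29e-13 over 2 lists, and adjusted p = 0.00368 with an estimated correlation). Other lists hold 5 of them. C1S, a complement protease, fell from 395 ± 1.91 to 54.4 ± 2.27 TPM (SD, n = 3), and C1R, CFB and CFI changed by -2.79, -3.27 and -2.13 on the log2 scale. After median-of-ratios scaling 21 fell and 1 rose. C5, a complement component, rose by 0.31, and its direction turned after the GC and length correction. SERPINA3, left out above because 2 rows share its symbol, went from 192 ± 3.87 to 14.3 ± 0.46 TPM in sum (SD, n = 3).

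Of 23 tested genes of gastrointestinal epithelium 18 rose and 3 fell (18 and 5 after scaling), with a median of 0.91 (camera adjusted p = 8.05e-04, and adjusted p = 0.0208 with an estimated correlation). No other list holds any of them. CEACAM6, a cell surface glycoprotein, rose from 478 ± 2.28 to 1782 ± 10.3 TPM and AGR2, a disulfide isomerase of mucus-secreting cells, from 491 ± 3.48 to 1740 ± 24.0 (SD, n = 3). The keratin KRT20 changed by 0.90 and the trefoil peptide gene TFF1 by 0.91. MUC1 (-2.85), PIGR (-2.25) and the trypsin inhibitor gene SPINK1 (-3.91) fell.

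Among 236 groups of genes that share a symbol stem, 14 passed camera with the preset correlation, 3 higher and 11 lower. With an estimated correlation none of the 14 passed (adjusted p = 0.653 to 0.663). Some of these groups share genes with the lists above: CXCL with NF-kB, MCM with DNA replication, IFI with interferon and KIF with mitosis. For those the counts are not independent of the lists. CXCL chemokines had 8 of 8 tested lower. SNX sorting nexins had 24 higher and 1 lower of 28 (20 and 3 after scaling), and MCM genes 10 higher and 0 lower of 11 (9 and 0 after scaling). KIF genes had 20 higher and 1 lower of 29 (17 and 4 after scaling). IFI genes had 0 higher and 7 lower of 8, ABCA genes 0 and 6 of 9, SERPINB genes 1 and 7 of 10, and CHD genes 1 and 8 of 10. IL genes had 8 higher and 16 lower of 37, so as deposited most did not fall past the threshold (8 and 20 after scaling). RNU small nuclear RNAs had 0 higher and 7 lower of 44, MIR genes 0 and 5 of 28, SNHG host genes 3 and 10 of 20, LINC genes 29 and 38 of 129 (16 and 55 after scaling), and RPL symbols, which include pseudogenes, 28 and 40 of 117 (10 and 58 after scaling).

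The tests of the NF-kB list, LUM and the chromosome windows were all chosen after those results were seen. The fall of the NF-kB list does not follow from the scaling of the libraries or from gene properties: its median was -3.39 after median-of-ratios scaling and -3.45 after correction for GC content and transcript length. A loss of leukocytes could lower the list through their own reads only if such reads were counted in the control libraries. The leukocyte markers other than CD68 and LYZ, which the tumour cells may express, had a median of 0.24 TPM in Ctrl, where LCN2 stood at 1423 TPM. Leukocytes of a xenograft come from the mouse host, and how many of their reads were counted as human is unknown. These values therefore cannot exclude a loss of host leukocytes, and its effect on the tumour cells was not tested. A lower inflammatory state of the tumour cells given rhLUM is a hypothesis, found and tested on the same libraries, and a difference between tumours unrelated to lumican stays open.

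The rise of LUM stood at 1.72 after median-of-ratios scaling, so scaling does not account for it. If more fibroblasts or other stroma had entered the rhLUM tumours, their other abundant transcripts should have risen with it. The other 11 tested fibroblast markers had a median of 0.26, and the largest rise among them was that of SPARC (0.94, from 16.8 ± 0.56 to 33.2 ± 1.09 TPM, SD, n = 3). The collagen COL1A1 rose from 3.30 ± 0.73 to 5.11 ± 0.92 TPM, a call lost on leaving out any library but Ctrl B or rhLUM B (adjusted p up to 0.0873), while DCN (-1.99) and COL6A3 (-1.97) fell. Which cells the LUM transcripts came from was not tested, since the tables do not separate human from mouse reads, and a change in the kind of stroma stays open.

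Of the 7 chromosome windows beyond the permuted bound, 4 stayed beyond it after correction for GC content and transcript length, so these trends do not account for the pattern as a whole. Medians of neighbouring windows correlated after the correction (r = 0.35 across windows, permutation p = 0.001, the smallest that 1000 permutations can give). A candidate explanation is that tumour cells of the groups differed in copy number, as clones of a cancer line can. Clusters of genes with shared regulation could give such windows too and were not tested. The chromosome 6 window that holds HLA-B went from -0.37 to -0.26, inside the corrected bound of 0.32, so it is not among the 4. After the correction 6 windows in all lay beyond that bound. They were neighbouring lower windows on chromosome 1 (-0.52 and -0.43), neighbouring lower windows on chromosome 3 (-0.35 and -0.44) and higher windows on chromosome 20. The latter, at 25248069 to 35519280 and 44531785 to 50192689, stood at 0.40 and 0.34. The chromosome 20 window between them stood at 0.22, inside the bound.

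Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 9870 genes and the highest of the others 1. For lists it called 12, and each of the 9 other splits called 4 to 8 while calling at most 1 gene. Every other split mixes libraries of both groups on each side. Part of the group difference then stays in the contrast and the rest enters the residual spread. The counts of the other splits therefore do not measure false calls, for genes or for lists.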
